A study of Mus musculus with 29 samples.

How the data were processed

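RNA from the livers of 12 mice was measured on 2-colour spotted arrays. All mice were fed fescue infected with an endophyte, a fungus of the grass that makes ergot alkaloids. In the group E+HS, 6 mice were kept under heat stress, for 14 d per the labels. In the group E+TN, 6 mice were kept at thermoneutral conditions. Titles of E+TN arrays carry SE+RT in place of E+TN, and do not say what RT stands for. Each group held 3 males and 3 females, marked by the first letter of the mouse name. In the labels, only arrays of E+HS females give an age, and no E+TN array gives a duration. Whether age and duration match between the groups is thus unknown. Per the labels, each array set 1 mouse against a universal mouse reference RNA, a commercial pool of RNA from cell lines, so that the groups are compared through the reference. Most mice were measured on several arrays, of which 1 carried the dyes swapped. In all, 29 arrays were used, counting 1 trial array of mouse M257 and 1 direct array of E+TN mouse F242 against E+HS mouse F201.

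The deposited value table has 1920 features per array and no scanner intensities, and the scanner, image analysis and normalization are not given in the sources used here. The deposited values of 27 reference and direct arrays are log2 ratios of channel 1 over channel 2, a scale read from the values themselves. The deposited swapped array of F201 holds log10 ratios: raised to base 10, 45.9% of its values were ratios of whole numbers, against 0.208% in base 2. The deposited trial array of M257 holds the linear ratio of mouse over reference. Per the labels, channel 1 held the mouse on all E+HS arrays and on forward E+TN arrays, and the reference on swapped E+TN arrays, and the values were checked for this order. As deposited, the swapped E+HS arrays correlated with the mean forward profile at r of 0.574 to 0.864 across features, and the swapped E+TN arrays at r of -0.792 to -0.528. Swapped E+TN arrays were therefore turned, so that every value is mouse over reference. The direct array was turned to E+HS over E+TN mouse from the channel order of its labels alone, and its values do not settle the direction.

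The 2 groups were deposited in different states. Without the trial array, which has neither, E+TN arrays lacked between 49 and 476 values each (median 101) and carried 4 to 24 values at 1 repeated ceiling above log2 16, which were set to missing. E+HS arrays had no missing and no ceiling value, and the direct array, with a mouse of each group, had 91 missing values and 14 at the ceiling. Why values are missing was not tested. Titles call these E+TN arrays and the direct array raw. No title of an E+HS array or of the trial array does so. Raised to base 2, 11.8% to 51.8% of values were ratios of whole numbers on the E+HS arrays held as log2 ratios. On the E+TN arrays without the trial array it was 1.65% to 4.68%. What raw stands for, and whether background was subtracted, is not given in the sources used here. Group and processing before deposit, background treatment included, cannot be told apart in these data. Arrays of the groups also differed in spread (median over arrays of the median absolute deviation 0.82 in E+HS and 1.27 in E+TN, log2).

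Gene names come from a platform annotation that lists 1090 of the 1920 features, 1083 with 1 symbol and 7 with several, which stay unnamed like the 830 that are not listed. Only 1 of the 1090 gene identifiers occurs in the mouse gene table (assembly GRCm38.p6), while 1001 of the listed symbols equal a mouse symbol. The identifiers are those of rat genes, so a symbol names the rat gene for which the annotation was made, and which mouse transcripts bind to the probe was not checked. No genome positions of the probes were used here. Members of close gene families, such as cytochromes P450 and sulfotransferases, may share signal on such probes.

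Values were brought to log2, each array was centred on its median, and features with the same symbol were averaged within an array. Per gene a dye effect was estimated from the 9 mice with both orientations as the mean over mice of forward minus swapped values, divided by 2, and removed. Forward and swapped means were then averaged with equal weight, giving 1 value per mouse. The technical arrays are no replicates, and n is the number of mice. A gene needed a value in at least 4 mice of each group, which left 1826 genes, 1013 of them named, with 1254 measured in all 12 mice. Tests were made with limma 3.58.1 in R 4.3.3 (linear model with moderated variances, two-sided, Benjamini-Hochberg adjustment over all genes, threshold 0.05). The effect of heat stress and the difference between the sexes came from a model with group and sex. The interaction and the effects within each sex came from a model with 4 groups of 3 mice and a common variance. Intensities were not used here, so signal over background is unknown. The number of mice and the variation between them limit the precision.

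Before the data were examined, 27 gene lists were fixed. They cover heat shock proteins and chaperones, endoplasmic reticulum stress, cytochromes P450, conjugation enzymes, antioxidant defence, fatty acid oxidation, cholesterol and fatty acid synthesis, gluconeogenesis and glycolysis, urea cycle and amino acid catabolism, acute phase response, and apoptosis. They also cover oxidative phosphorylation, ribosomal proteins, ubiquitin and proteasome, ion transporting ATPases, bile acid synthesis and transporters, hepatocyte markers, male-biased liver genes, and the response to prolactin, growth hormone, thyroid hormone and glucocorticoids. The other 8 lists had fewer than 5 measured members and were not tested: cell division, macrophage and leukocyte, stellate cell, endothelial, cholangiocyte and erythroid markers, female-biased liver genes, and circadian clock genes. The other 19 lists were tested with camera (preset correlation 0.01), with camera at an estimated correlation and with fry on genes measured in all mice. The level of a list in a mouse is the median over the members measured in that mouse, which can be fewer in E+TN mice. Group differences of levels were tested with exact permutation of the 12 mice (924 assignments, two-sided, adjusted over the 19 lists).

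Genes are named by a rule fixed beforehand. For each comparison it takes up to 10 genes in each direction that pass the threshold and have the largest differences, or else the passing ones and those with the smallest p, up to 5 in each direction. For each list described it takes up to 4 members with the smallest p.

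The procedure was tested on simulated data with the missing values and array numbers of this series. For heat stress over 1826 genes, limma called 38.8% of 67 genes simulated with a log2 difference of 1, 65.7% of 67 genes with 1.5, and 83.3% of 66 genes with 2, with 1 false call among 1626 unchanged genes. All 200 genes were changed in 1 simulation, and with Benjamini-Hochberg adjustment the share called depends on how many genes change. The noise of a gene had the same size in every mouse, without the difference in spread between the groups. These shares thus need not hold for the real comparison. A simulated shift of 0.5 in 1 list alone was recovered in 17 of 20 draws (median adjusted p 0.000623). Together with 200 changed genes elsewhere it was recovered in 0 of 20 draws (median adjusted p 0.644), so the list test can miss a shift where many other genes change. Noise was drawn independently for each gene, while members of the lists are correlated in the real data. The estimated correlation was 0.30 for oxidative phosphorylation, the shifted list, and 0.52 for heat shock proteins. The draws thus do not show how the list test performs at such correlations. Alternatives to each step were fixed beforehand and others were added after seeing the data. Also chosen after values were seen were the exact test of list levels, the estimated correlation and fry under other scalings, the opposite direction of the direct array, the simulated list shifts, dye removal as the setting for the direct array, and which lists are shown with members.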

Results

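Liver expression was profiled in 12 mice on an endophyte-infected fescue diet, 6 of them under heat stress (E+HS) and 6 at thermoneutral conditions (E+TN), with 3 males and 3 females in each group. The E+HS mice were measured on 14 arrays against the reference RNA and the E+TN mice on 13, with 1 more trial array and 1 direct array. Mice had 1 to 3 arrays, and M221 (E+HS), F212 and F242 (E+TN) had 1 each. All values are log2 ratios of mouse over reference RNA from a pool of cell lines. Hepatocyte markers were above the reference in the mean for 26 of 29 genes, and ribosomal proteins for 0 of 49.

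Repeated arrays of 1 mouse in 1 orientation differed by a median SD of 0.36 over genes (0.22 to 0.41 in 6 pairs), while mice of a group differed by a median SD of 0.53 in E+HS and 0.61 in E+TN. The number of mice and the variation between them limit the precision: the median SE of a difference between the groups was 0.36, and the median half-width of its 95% interval 0.79. Profiles were narrower in E+HS than in E+TN, with an SD over genes per mouse of 1.19 ± 0.22 (SD, n = 6) against 1.52 ± 0.33 (SD, n = 6), a difference of -0.33 that did not pass an exact permutation test (p = 0.0714). Across genes, which are not independent replicates, the heat stress difference correlated with the mean level over reference at r = -0.319. Genes far above the reference thus tended to read lower in E+HS, and among the arrays against the reference only those of E+TN, the trial array excepted, have missing values and values at a ceiling.

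The first question was what heat stress adds to the infected diet. Among the genes reading higher in E+HS, Car3, carbonic anhydrase 3, stood at 4.52 ± 0.56 (SD, n = 6) against 3.44 ± 0.61 (SD, n = 6) in E+TN, a log2 difference of 1.08 (SE 0.27). Ephx2, the soluble epoxide hydrolase, differed by 1.27 (SE 0.35), and Csrp3, a muscle LIM protein, by 1.19 (SE 0.30). Nos2, the inducible nitric oxide synthase, differed by 0.98 (SE 0.28) and Erp29, a chaperone of the endoplasmic reticulum, by 0.89 (SE 0.26, n = 6 and 5). Thrsp, a thyroid hormone responsive regulator of fat synthesis, differed by 1.31 (SE 0.40). Among the genes reading lower in E+HS were Pgk1, a glycolytic kinase, at -1.48 (SE 0.37), Agt, the precursor of angiotensin, at -1.38 (SE 0.39), and Arg1, the last enzyme of the urea cycle, at -1.32 (SE 0.41). Cyp3a18, a cytochrome P450, differed by -1.25 (SE 0.36), and Ces1e, a carboxylesterase, by -1.33 (SE 0.41), where 1 mouse, F232, lay far below the others. None of these genes passed: limma called 0 of 1826 genes, and the lowest adjusted p was 0.560, the value of all 11 genes above. At an unadjusted p under 0.05, limma gave 145 genes, 63 higher and 82 lower, where chance gives 91.3. That number was 63 with dye balance as a covariate, 81 without centring and 251 with weights per mouse. With quantile normalization 4 genes passed, among them Car3 (1.82) and Ephx2 (1.73), both at adjusted p = 0.0282.

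**Figure D1:**
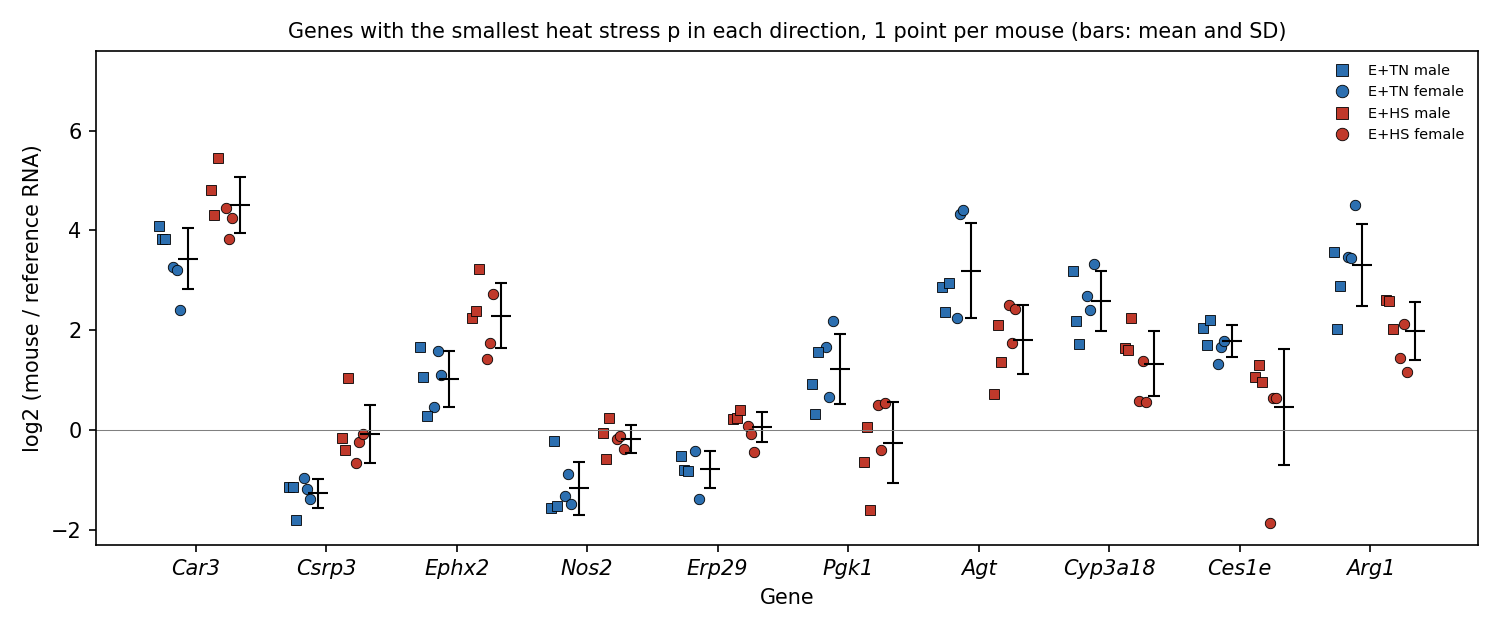
Log2 ratio of mouse over reference RNA (vertical axis) for 10 named genes, the 5 with the smallest p in each direction (horizontal axis), 1 point per mouse, with bars for mean and SD of each group. Car3 stood at 4.52 in E+HS and 3.44 in E+TN and Pgk1 at -0.26 and 1.22, while F232 lay at -1.86 for Ces1e; none of these differences passed the adjusted test.

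Gene lists gave 0 of 19 past the threshold for heat stress with camera, and 0 with an estimated correlation or with fry. Enzymes of the cytochrome P450 system, which oxidize drugs, steroids and toxins, had the most separated levels. The list level per mouse was 0.98 ± 0.33 (SD, n = 6) in E+HS and 1.72 ± 0.21 (SD, n = 6) in E+TN, a difference of -0.75 (exact permutation p = 0.00433, adjusted p = 0.0823). Of its 21 members, 16 read lower and 5 higher, with a median of -0.37 (camera adjusted p = 0.230) that turned to 0.07 with quantile normalization and was -0.08 with the 9 mice that have both dye orientations and -0.23 without M203. Cyp2f4 differed by -1.02 (SE 0.37), Cyp2a2 by -1.52 (SE 0.75), where 1 mouse, F242 at 8.70, lay far above the others (-0.46 without it), and Cyb5r3, an electron donor of the system, by 0.87 (SE 0.37). The level difference was -0.53 without centring (exact p = 0.145), -0.27 with arrays scaled to equal spread (exact p = 0.264), -0.30 with quantile normalization (exact p = 0.203) and -0.57 with a slope per mouse removed (exact p = 0.0195). Only 12 of the list's 21 members were measured in all mice, and the missing values are in E+TN. Its level is thus not taken over the same genes in every mouse, which these differences and exact p-values do not allow for. Conjugation enzymes, which attach sulfate, glucuronide or glutathione, had a median of -0.12, 17 of 26 lower, which turned to 0.16 without centring, 0.05 with equal spread and 0.10 with quantile normalization. Within it Sult1a1 differed by -1.28 (SE 0.41) and Sult2a6 by -1.30 (SE 0.53, and -0.82 without F212), both sulfotransferases. Centring matters here because the median over all genes moved from -0.10 to 0.14 when arrays were left uncentred.

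The measured heat shock proteins and chaperones, which keep other proteins folded, did not read higher as a list under heat stress. Hspa1a, Hspa1b, Hspb1, Hsph1, Dnajb1, Hsp90aa1 and Bag3 of the fixed list were not among them, so these genes were not tested. Of 14 members 12 read lower, with a median of -0.23 (camera adjusted p = 0.433), and the levels were -0.87 ± 0.53 (SD, n = 6) in E+HS and -0.80 ± 0.34 (SD, n = 6) in E+TN. The members with the smallest p were Serpinh1, a collagen chaperone, at -1.48 (SE 0.71), Dnajc3 at -0.53 (SE 0.25), Hspbap1 at -0.52 (SE 0.38) and Hspa8, a constitutive chaperone, at -0.89 (SE 0.72). Single mice carry much of this: Serpinh1 was -0.72 without F212, and without M221 Hspbap1 was -0.24, Hspa8 -0.27 and the list's median -0.06; without F231 the median was -0.08. The list's median turned to 0.06 without mice M221 and F212 together, while with equal spread it was -0.27 with 13 of 14 lower and passed camera (adjusted p = 0.0287, but 0.458 with an estimated correlation). Endoplasmic reticulum stress genes had a median of -0.29 with 10 of 11 lower (adjusted p = 0.230), and apoptosis genes one of -0.54 with 8 of 9 lower (adjusted p = 0.230), both negative under every scaling tried. Antioxidant genes had a median of -0.17 with 21 of 29 lower (adjusted p = 0.508), which turned to 0.04 without centring.

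Of the 13 genes of cholesterol and fatty acid synthesis 9 read higher, the largest share of any list tested, at a median of 0.10 (camera adjusted p = 0.230). It held Thrsp, Insig1, a brake on sterol synthesis, at 0.58 (SE 0.47), and Idi1, an isomerase of the sterol pathway, at -0.70 (SE 0.47), which was -0.23 without F212. Insig1 ranged from 0.34 without M257 to 1.04 without M222. The median stayed above 0 under every scaling tried, and was -0.02 without M257. The list passed camera with equal spread (0.22, adjusted p = 0.0287, but 0.458 with an estimated correlation), with the direct array added (0.29, adjusted p = 0.00907) and with weights per mouse (0.32, adjusted p = 0.0299). The call with the direct array rests on the direction in its labels, and a fit with that array turned was not made. Fatty acid oxidation genes had a median of -0.21 with 13 of 24 lower (adjusted p = 0.433), which lay above 0 without centring, with equal spread (0.12) and with quantile normalization (0.02). Hadhb, of the mitochondrial beta-oxidation complex, differed by -1.15 (SE 0.41), Decr2, a peroxisomal reductase, by -0.69 (SE 0.25), and Acox2, a peroxisomal oxidase, by 0.98 (SE 0.36). In gluconeogenesis and glycolysis, 11 of 17 members were lower at a median of -0.16 (adjusted p = 0.663), which turned to 0.08 without centring, 0.03 with equal spread and 0.05 with quantile normalization. Adjusted over the list alone, 1 member passed, Pgk1, which fell; over all genes 0 passed. G6pc1, the last enzyme of glucose release, differed by 0.76 (SE 0.29).

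Urea cycle and amino acid catabolism had a median of -0.35 with 17 of 26 lower (adjusted p = 0.599), but passed camera in the other direction with equal spread (0.21, adjusted p = 0.00853, but 0.458 with an estimated correlation) and quantile normalization (0.23, adjusted p = 0.00877, but 0.485), and stood at 0.01 with a slope per mouse removed. Otc, of the urea cycle, differed by -0.83 (SE 0.35) and Gls2, the liver glutaminase, by -0.63 (SE 0.26). Acute phase genes, made by the liver in inflammation, had a median of -0.38 with 16 of 21 lower (adjusted p = 0.297), which turned to 0.04 with equal spread and 0.01 with quantile normalization. Fga, a fibrinogen chain, differed by -0.66 (SE 0.30), and by -0.40 without F212. Hepatocyte markers had a median of -0.52 with 22 of 29 lower (adjusted p = 0.230), which turned to 0.17 with equal spread, where the list passed camera as higher (adjusted p = 0.0104, but 0.458 with an estimated correlation), and to 0.03 with quantile normalization. It passed as lower without F201 (-0.51, adjusted p = 0.0401), without F202 (-0.71, adjusted p = 0.0289) and with every feature tested by itself (adjusted p = 0.0421). Among them Apoh, a plasma glycoprotein, differed by 1.40 (SE 0.50) and Apob, of lipoproteins, by -1.23 (SE 0.55). Adjusted over the list alone, 0 members passed in the other 18 lists.

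The housekeeping lists read slightly lower. Oxidative phosphorylation had a median of -0.16 (18 members, adjusted p = 0.774, 0.06 without centring) and ubiquitin and proteasome one of -0.16 (32 members, adjusted p = 0.328, 0.05 without centring, -0.23 with equal spread at adjusted p = 0.0348, but 0.589 with an estimated correlation). Ion transporting ATPases had a median of -0.15 (5 members, adjusted p = 0.663), which turned to 0.11 without centring. Ribosomal proteins had a median of -0.11 with 33 of 49 lower (camera adjusted p = 0.663), which turned to 0.11 without centring. With equal spread it was -0.61 (adjusted p = 2.35e-10), with quantile normalization -0.32 (adjusted p = 2.45e-05) and with a slope per mouse removed -0.41 (adjusted p = 3.18e-05). With an estimated correlation these 3 calls were lost (adjusted p = 0.458, 0.485 and 0.795), as they were with fry (0.495, 0.421 and 0.570). Bile acid synthesis and transporters had a median of -0.05 and a mean of -0.09 over 22 members while the test pointed up (adjusted p = 0.774), and its median lay above 0 under the other 4 scalings. The hormone response list had a median of -0.17 and a mean of -0.06 over 10 members, its test also pointed up (adjusted p = 0.767), and its median also lay above 0 under the other 4 scalings. Male-biased liver genes had a median of 0.01 over 5 members (adjusted p = 0.592).

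The sexes were compared over both groups. Male-biased liver genes, fixed as a list beforehand, were lower in females. The list level was 0.34 ± 0.25 (SD, n = 6) in females and 1.25 ± 0.32 (SD, n = 6) in males, a difference of -0.91 (exact permutation p = 0.00216, the smallest these mice can give, adjusted p = 0.0411). The highest female stood at 0.68 and the lowest male at 0.91, so the sexes did not overlap. Only 3 of the list's 5 members were measured in all mice. Its level is thus not taken over the same genes in every mouse, which the exact p does not allow for. Of its 5 members 4 were lower in females, at a median of -1.01, the exception being Egfr, named here after its value was seen. Camera passed the list (adjusted p = 6.78e-06), but not with an estimated correlation on the 3 members measured in all mice (adjusted p = 0.117), nor with fry (adjusted p = 0.0669). Adjusted over the list alone, 3 members fell in females, while over all genes 0 passed. Gstp1, a glutathione transferase, stood at -0.07 ± 0.37 (SD, n = 6) in females and 1.30 ± 0.38 (SD, n = 6) in males, a difference of -1.37 (SE 0.27, limma adjusted p = 0.372). Hsd3b5, a steroid reductase of male mouse liver, differed by -1.18 (SE 0.34) and Ugt2b1, a glucuronosyltransferase, by -1.01 (SE 0.33). Mup4, a major urinary protein, differed by -0.64 (SE 0.77), but by 0.04 without M221. The list's median stayed negative under every scaling, between -1.07 and -0.54, and the exact p was 0.0152 without centring and 0.00216 under the other 3.

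**Figure D2:**
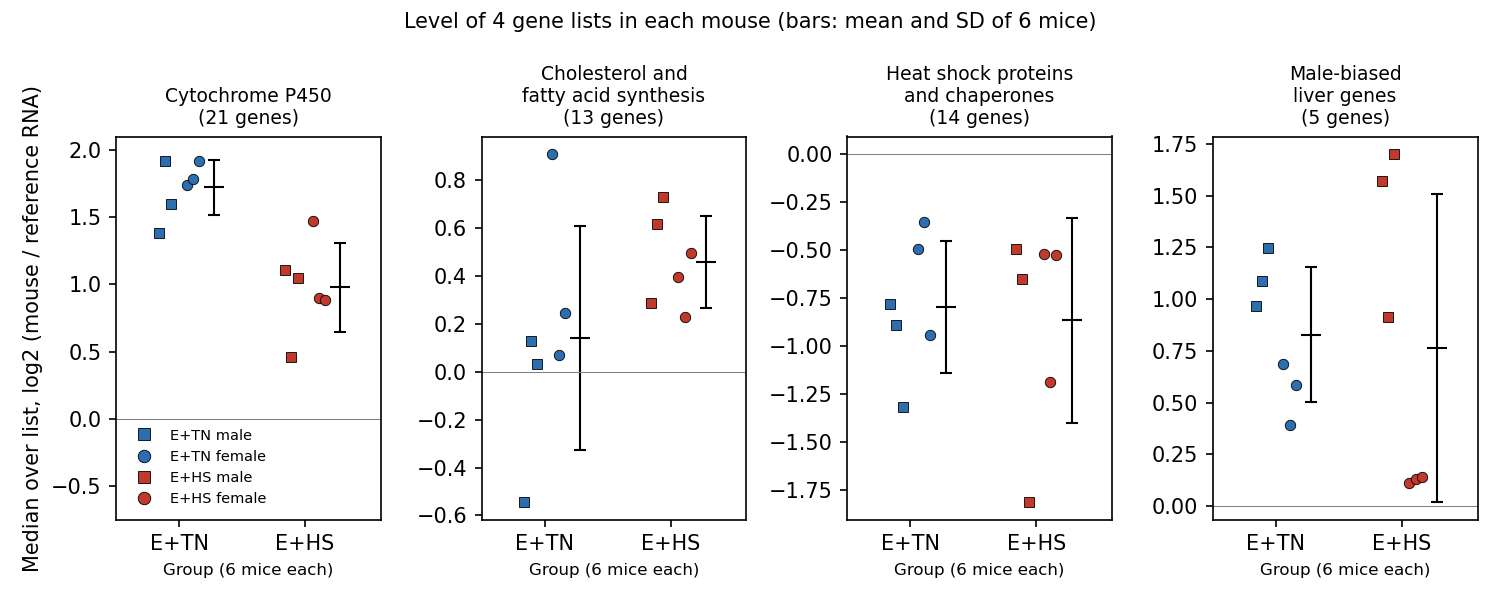
Median log2 ratio of mouse over reference over the members of 4 gene lists (vertical axes), 1 point per mouse, by group (horizontal axes, 6 mice each) and sex (squares male, circles female), with bars for mean and SD of 6 mice. Cytochrome P450 levels were 0.98 in E+HS and 1.72 in E+TN, a difference of -0.75 that was -0.30 with quantile normalization (exact permutation p = 0.203). The median of the differences of single members, another measure, was -0.37 and turned to 0.07 with quantile normalization. Male-biased genes stood at 0.34 in females and 1.25 in males.

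For single genes, limma called 0 of 1826 between the sexes, with 76 at an unadjusted p under 0.05, 42 higher and 34 lower in females, where chance gives 91.3. The lowest adjusted p was that of Gstp1. Cyp2b3, a cytochrome P450, was next at 1.23 (SE 0.28, adjusted p = 0.573). A fit to single arrays with mouse as a random block called both: Gstp1 stood at -1.46 (adjusted p = 0.000154), and the female minus male log2 difference of Cyp2b3 was 1.29 (adjusted p = 0.0336). Its degrees of freedom come from arrays, which are technical replicates, and 1 correlation within mice was used for all genes. Gclm, a subunit of the enzyme that starts glutathione synthesis, differed by -1.25 (SE 0.34), and Car3 by -0.82 (SE 0.27), which turned to 0.41 with equal spread. Mt1, a metallothionein, differed by 1.32 (SE 0.43), Mx2, an interferon-induced GTPase, by 0.82 (SE 0.25), Psmb3, of the proteasome, by 1.08 (SE 0.35), and Pnliprp1, a lipase-related protein, by 0.72 (SE 0.23). Cytochromes P450 had a median of 0.25 with 16 of 21 higher in females (camera adjusted p = 0.110), and adjusted over the list alone 1 passed, Cyp2b3, which rose. With equal spread the list passed camera (0.42, adjusted p = 0.000110), as did hepatocyte markers (0.68, adjusted p = 8.08e-06) and ribosomal proteins (-0.61, adjusted p = 3.69e-11), but with an estimated correlation the adjusted p was 0.464, 0.449 and 0.449. Conjugation enzymes had a median of -0.17 with 16 of 26 lower (adjusted p = 0.0905), which turned to 0.05 with equal spread and passed with quantile normalization (-0.21, adjusted p = 0.0322, but 0.150 with an estimated correlation), and Gstp1 was the 1 member past adjustment over the list alone. Of the sulfotransferases, Sult2a1 differed by 1.18 (SE 0.64), with F242 at 3.15 far above the others (0.27 without it), and Sult1c2 by 0.48 (SE 0.25). Heat shock proteins had a median of 0.25 with 13 of 14 higher in females (adjusted p = 0.117) and the proteasome list one of 0.23 (adjusted p = 0.0980), which turned to -0.01 and -0.08 with equal spread. All 5 ion transporting ATPases were higher in females, at a median of 0.42 (adjusted p = 0.0980). For fatty acid oxidation (0.05) and oxidative phosphorylation (0.09) the median was above 0 while the test pointed down, and fatty acid oxidation turned to -0.04 without centring and oxidative phosphorylation to -0.15 with equal spread.

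Whether the effect of heat stress differed between the sexes was tested as an interaction. Limma called 2 of 1826 genes, and each rests on 1 mouse. Gatm, which makes the precursor of creatine, had a difference of 6.87 (SE 0.87, 95% interval 4.94 to 8.80, adjusted p = 0.0194) between the effects in females and males. It was measured in only 1 E+TN female, F202, at -5.23, while the other mice lay between -1.64 and 1.22. The unnamed feature 1417 had a difference of 4.93 (SE 0.75, adjusted p = 0.0478), also from 1 measured E+TN female, F212, at -4.93. Within females the same 2 features passed, at 5.43 (SE 0.71) and 4.79 (SE 0.61), both at adjusted p = 0.0129. When a gene needed at least 2 mice in each group and sex, limma called 0 of 1712 for the interaction and 0 within females. Without that need, leaving out 1 mouse at a time gave 0 to 31 genes for the interaction and 0 to 76 within females. At an unadjusted p under 0.05 limma gave 111 genes for the interaction and 174 within females, where chance gives 91.3.

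Other genes did not pass for the interaction. Rps26, a ribosomal protein, had a difference of -6.14 (SE 1.07, adjusted p = 0.0729), again with F202, at 3.75, as the only measured E+TN female. Pdia4, a disulfide isomerase of the endoplasmic reticulum, had one of 4.19 (SE 0.75, adjusted p = 0.0634), with all 3 E+TN females below 0 and all 3 E+TN males above 1. Zfp354a, a zinc finger protein, differed by 3.74 (SE 0.80), and the proteasome ATPases Psmc4 and Psmc5 by 2.87 (SE 0.67) and 2.20 (SE 0.62). Fdps, which makes farnesyl diphosphate for sterol synthesis, differed by -2.42 (SE 0.69), Mapre1, a microtubule end protein, by -1.95 (SE 0.65), and Itih3, an acute phase plasma protein, by -1.71 (SE 0.59). Of 19 lists 0 passed for the interaction or within females. Ribosomal proteins had an interaction median of -0.37 with 38 of 49 members lower (camera adjusted p = 0.0683), and acute phase genes one of -0.61 with 16 of 21 lower (adjusted p = 0.0984), which turned to 0.09 with equal spread. Within females the lowest adjusted p was 0.117, for P450 enzymes (median -0.44), acute phase genes (-0.65) and ribosomal proteins (-0.38), and the first 2 turned to 0.25 and 0.11 with equal spread. In that scaling ribosomal proteins were at -1.46 (camera adjusted p = 7.96e-26, fry 0.0217, estimated correlation 0.386), and hepatocyte markers turned from -0.54 to 0.74 (camera adjusted p = 2.48e-05, estimated correlation 0.540). Adjusted over the list alone, 1 gene passed in each of the endoplasmic reticulum stress and proteasome lists (higher) and the ribosomal list (lower) for the interaction. Within females it was 1 in each of the P450 and urea cycle lists (lower) and the fatty acid oxidation list (higher).

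Within males, limma called 0 of 1826 genes (lowest adjusted p 0.881), with 91 at an unadjusted p under 0.05, where chance gives 91.3. Genes of cholesterol and fatty acid synthesis rose as a list in heat-stressed males by camera (adjusted p = 0.0120), with 11 of 13 members higher and a median of 0.36. The call was lost with an estimated correlation (adjusted p = 0.985) and with fry (adjusted p = 0.992), and adjusted over the list alone 0 members passed. Over the list alone, 1 endoplasmic reticulum stress gene passed, lower in heat-stressed males, in a list with a median of -0.22 (adjusted p = 0.0606) that turned to 0.55 without centring. Fdps stood at 1.34 ± 0.49 (SD, n = 3) in E+HS males and -0.16 ± 0.84 (SD, n = 3) in E+TN males, a difference of 1.50 (SE 0.49). Thrsp differed by 1.38 (SE 0.58), Acly, which makes acetyl-CoA for fat synthesis, by 0.93 (SE 0.47), and Lss, the lanosterol synthase, by 0.67 (SE 0.41), which was 0.36 without M257. Without the E+TN male M257 the list's median was 0.01 (adjusted p = 0.457), and without the E+HS male M203 it was 0.42 (adjusted p = 0.0922). The list did not pass as different between the sexes, at an interaction median of -0.56 (adjusted p = 0.0984). With 3 mice against 3, an exact permutation test of levels cannot go below p = 0.10.

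On the direct array, E+HS female F201 was set against E+TN female F242 without the reference. It compares these 2 mice and has no replicate, and its direction rests on the labels alone, so that the opposite order would turn the sign of every value given for it. Across 1557 genes its ratios correlated with the indirect difference of the same mice at r = 0.158 (95% interval 0.109 to 0.206, Spearman 0.185), and at r = 0.0945 without removal of the dye effect. The interval counts genes as independent, which they are not, and does not measure spread over arrays or mice. Among 161 genes beyond 1 in size on the direct array, 94 (58.4%) had the same sign in the indirect difference, and in the opposite direction it would be 67 (41.6%). Cytochromes P450 had a median of -0.60 on the direct array, at percentile 1.42 of 10000 random lists of genes with like levels over reference, and -0.81 in the indirect difference; the opposite direction gives 0.60 at percentile 98.5. Of the 19 lists, 6 lay in the outer 5% of random lists, both sides together, so this position is not specific to the P450 list. Cholesterol and fatty acid synthesis had a median of 0.86, with 12 of 13 members higher in F201, at percentile 100, against 0.09 in the indirect difference, and in the opposite direction 1 of 13 would be higher, at percentile 0. With the group difference fitted without both mice, the direct array correlated at r = 0.0277 over 1704 genes.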

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

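The comparison of other splits was fixed before the data were seen, as was the outlier search. The look at the mice of the highest splits and the weighing of the P450 list and of the F231 array were chosen after seeing results. So was the use of the direct array in weighing the cholesterol list.

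Dixon's test on 100 groups of values (the genes named for a comparison, list levels, and the spread and correlation of each mouse, by group) found 4 outliers, where chance gives 5. All are E+HS mice. Csrp3 in M221 stood at 1.03, with the others at -0.65 to -0.09, and Ces1e in F232 at -1.86, with the others at 0.64 to 1.31. The SD over genes of M221 was 1.62, against 0.990 to 1.18 in the others, and its correlation with the other mice of its group 0.727, against 0.865 to 0.911. M221 has 1 array only. None of these mice was left out.

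Gatm, with a heat stress effect in females minus that in males of 6.87, and feature 1417, with 4.93, are the only genes called in any comparison of the planned setting. Each rests on 1 E+TN female, F202 at -5.23 and F212 at -4.93, because the other 2 females of that group have no value. In the fit, E+TN arrays lack values and E+HS arrays lack none. Why values are missing in that group was not tested.

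Mice were also split at random into other groups of the same size, and the calls counted as in the real comparison. The splits counted include the real one. Where the real count is 0, every split gives as many, so that the number of splits says nothing. This holds for the genes and lists of heat stress (100 of 100 each, highest other 114 and 5), the genes of the sexes (100 of 100, highest other 116) and the lists of the interaction (100 of 100, highest other 6). It also holds for the lists within females (10 of 10, highest other 2) and the genes within males (10 of 10, highest other 0). The 1 list of the sexes was reached in 65 of 100 splits (highest other 6) and the 2 genes of the interaction in 5 of 100 (highest other 3), so chance is not excluded for these counts. Within females the 2 genes (1 of 10, highest other 1) and within males the 1 list (9 of 10, highest other 4) have too few splits for a share under 0.05. The male-biased list by itself was as strong in 1 of 100 splits, the real one, with a highest other value of 5.14 against 6.45 (minus log10 of p), which excludes a random division of the mice at that share. At least 1 list passed the threshold in 58 of 100 splits for heat stress, in 65 for sex (the real one included) and in 57 for the interaction. A single list call by camera is therefore weak evidence here.

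A few splits gave far more genes than the real groups, up to 114 for heat stress and 116 for sex. The first is the division by sex with M221 and F212 exchanged, and the second the division by group with the same 2 mice exchanged. Each fit kept the real sex or group as a term. These splits therefore set M221 and F212 against the other mice of their sex or group. Both mice have 1 array and broad profiles (SD over genes 1.62 and 2.02). The fits call genes in which these 2 mice differ from those others in opposite directions. A breadth shared by both does not by itself give such genes. M221 has only a forward array and F212 only a swapped one. The high counts thus reflect how these 2 mice differ from the rest, and cannot tell an exchange from other causes. Whether the 2 samples were exchanged stays open. The male-biased level places M221 (1.70) with the males and F212 (0.39) with the females. The 4 female-biased genes do not: M221 was at 0.67, the highest of all mice (other males -0.83 to -0.13). F212 was at -0.32, the lowest female, but close to F202 at -0.30. Results without both mice are given with the other settings.

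Lower P450 levels in E+HS may come from heat stress or from the processing of the deposited values. The trial array, deposited as linear ratios, minus the same mouse's log2 array gave a list median of -0.0401 (95% interval -0.185 to 0.0452 from resampling list members), and 1 array cannot tell. If the spread of array values made the difference, the list median should lose more than 50% of its size under all scalings of the spread: it was -0.01, 0.0667 and -0.12 with equal spread, quantile normalization and a slope removed, which fits. The difference in level per mouse did not vanish, at -0.27, -0.30 and -0.57, but levels can rest on fewer members in E+TN mice. If heat stress made it, the direct array should show it: its median was -0.598, which fits as well, but only if the labels give its direction rightly, and it compares 2 mice. The pattern stays open.

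Higher cholesterol and fatty acid synthesis in E+HS males was weighed likewise. Trial minus log2 array gave 0.0691 (95% interval -0.0504 to 0.115 from resampling list members), which cannot tell. That 1 male decides the value fits: the median was 0.0132 without M257, against 0.21 to 0.46 without any 1 of the others. For heat stress the direct array gave 0.861, which cannot tell because it compares females and its direction rests on the labels.

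The swapped array of F231 carries the dye signature of forward arrays. Its correlation with the dye effect of the other mice was 0.372, where 16 forward arrays gave 0.0759 to 0.536 and 10 other swapped arrays -0.396 to 0.119, which fits a wrong dye label. The array correlated with its own forward array at r = 0.815, against 0.481 to 0.765 in the other mice. This cannot exclude a poor hybridization, because forward and swapped arrays carry opposite dye effects, which a wrongly labelled array would not. Repeated arrays of 1 mouse in 1 orientation correlated at 0.595 to 0.859, a range that holds the value of F231. No biological explanation was tested, because the dyes have none. The label was kept, and results with the array read as forward are given with the other settings.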

How the results depend on the processing

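Of 35 alternatives, 31 were planned, and 4 were added after seeing the data: named genes alone, a slope per mouse removed, M221 and F212 left out, and the F231 swapped array read as forward. The exact test of list levels, the need for 2 mice per group and sex, and the estimated correlation under other scalings were also chosen after seeing the data. Estimated correlation and fry were planned for the lists under heat stress and applied to the other comparisons later. Of 2348 recomputed single-gene values 2297 stayed, 7 became weaker, 29 stronger and 15 reversed. Numbers of genes and lists are those past an adjusted p of 0.05, and the cause of a change was not tested unless stated. No paired analysis was possible because no mouse name occurs in both groups and the labels pair no mice.

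In the planned setting, limma called 0 genes and camera 0 lists for heat stress, 0 and 1 for sex, 2 and 0 for the interaction, 2 and 0 within females, and 0 and 1 within males.

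Without centring, the interaction gave 0 genes and 1 list, and females 1 gene.

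With arrays scaled to equal spread, heat stress gave 6 lists, sex 8, the interaction 3 and females 30 genes and 5 lists. The hepatocyte list turned to 0.17 (adjusted p = 0.0104). In heat stress Mgst1 turned to 0.40, Scd2 to -0.000818, Gys2 to 0.0255, Itih4 to 0.14, C3 to 0.13 and Ahsg to 0.17, and Car3 between the sexes to 0.41.

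Quantile normalization gave 4 genes and 2 lists for heat stress, 2 lists for sex, 1 list for the interaction, and 0 genes and 4 lists within females. The hepatocyte list turned to 0.0347, the P450 list to 0.0667, Mgst1 to 0.13, Gys2 to 0.0222 and Itih4 to 0.0145.

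Without dye removal, the interaction gave 1 gene and 1 list and males 2 lists, and the direct array correlated at r = 0.0945. With dye balance as a covariate, sex gave 2 lists, the interaction 1 gene and 1 list, and females 1 gene and 1 list.

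With every array in the fit and mouse as random block, sex gave 2 genes and 2 lists, the interaction 4 genes and 2 lists, females 6 genes and 1 list, and males 2 lists. With the direct array added, heat stress gave 1 list, sex 2 genes and 2 lists, the interaction 0 genes and 1 list, and females 1 list. The direction of that array rests on its labels.

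With the 9 mice that have both orientations, the interaction gave 23 genes and 1 list, females 32 genes and 1 list, and the heat shock list turned to 0.0179. Males gave 1 list, ribosomal proteins, while the cholesterol list was lost (adjusted p = 0.0781). In this setting F202 is the only E+TN female, since F212 and F242 have 1 array each.

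With forward arrays alone, the interaction gave 1 gene and 1 list, females 1 gene and 1 list, and males 0 lists, with the cholesterol list at adjusted p = 0.240. Cbs turned to -0.0360 for heat stress and Hfe to 0.0836 for the interaction. With swapped arrays alone, sex gave 0 lists, the interaction 6 genes and 1 list, and females 10 genes. The heat shock list turned to 0.0839 and Insig1 to -0.25. Males gave 1 list, ribosomal proteins in place of the cholesterol list (adjusted p = 0.333).

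With the 1140 genes that have a value on every array, the interaction and females gave 0 genes and males 0 lists (cholesterol adjusted p = 0.0551). Without a filter, females gave 7 genes. With at least 2 mice per group and sex, the interaction gave 0 genes, by construction without Gatm and feature 1417.

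With every feature tested by itself, heat stress gave 1 list, sex 3 and the interaction 1 gene. With weights per mouse, heat stress gave 1 list, sex 4, the interaction 1, females 1, and males 3 genes and 2 lists, and the heat shock list turned to 0.0536. With the genes nearest to the reference left out, sex gave 2 lists.

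Among the added settings, named genes alone gave 2 lists for sex, 1 gene within females and 2 lists within males. With a slope per mouse removed, heat stress gave 1 list, sex 2, the interaction 6 genes and 1 list, females 4 genes and 1 list, and males 2 lists. Without M221 and F212, sex gave 2 lists, the interaction 1 list, and females 8 genes and 1 list. The heat shock list turned to 0.0585 and Mup4 to 0.0373. Males gave 1 list, ribosomal proteins in place of the cholesterol list (adjusted p = 0.0501). With the F231 swapped array read as forward, the interaction gave 1 gene. With an estimated correlation and with fry, sex and males gave 0 lists. With an estimated correlation 0 lists passed in any comparison under any of the 4 other scalings.

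The trial array, a plain mean over arrays, trend and robust variances, a model without sex, and Spearman in place of Pearson changed no call. The exact test of list levels, made for heat stress and sex alone, gave 0 and 1 lists. Within males it was not made, since 3 mice against 3 cannot pass it.

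Leaving out 1 mouse at a time gave 0 to 0 genes and 0 to 1 lists for heat stress, with 1 without F201 or F202 (hepatocyte markers, lower). Sex gave 0 to 0 genes and 0 to 3 lists: 3 without M234, 2 without F231, M257, M222 or F212, and 0 without F202 or F242, where the male-biased list had fewer than 5 members. The interaction gave 0 to 31 genes: 31 without F202, 8 without F242, 4 without F212, 2 without M221 and 0 otherwise. It gave 0 to 1 lists, with 1 without F232, M221, F201, F202, M222 or F212. Females gave 0 to 76 genes: 76 without F202, 9 without F242, 5 without M221, 3 without F232, 2 without M203, M234 or F212, and 0 otherwise. They gave 0 to 3 lists, with 3 without F232 and 1 without F202. Males gave 0 to 0 genes and 0 to 2 lists, with 2 without M234 or M221 and 0 without M203 or M257. Mup4 between the sexes ranged from -1.05 to 0.0373 (reversed without M221), and the cholesterol list for heat stress from -0.0198 to 0.20 (reversed without M257). The cholesterol list in males ranged from 0.0132 to 0.46, with an adjusted p of 0.457 without M257 and 0.0922 without M203.

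The male-biased list stayed between -1.18 and -0.54 (camera adjusted p 5.29e-10 to 0.000747 at the preset correlation) in settings with at least 5 members. With an estimated correlation its call was lost (adjusted p = 0.117, and between 0.120 and 0.449 under the other scalings), as it was with fry (0.0669). It could not be tested without F202, F242, M201 or M257, with the 9 mice, with 1 orientation alone, or with genes on every array. In these settings the conjugation enzymes passed as lower in females without M201 or M257, with the 9 mice, with forward arrays alone and with genes on every array.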

Other observations

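The observations here were chosen after seeing the results, and no test among them was planned except those of the lists fixed beforehand.

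Genes of other liver cell types were few on this array. The 3 macrophage and leukocyte markers had a heat stress median of -0.15 and a sex median of 0.19, the 3 stellate cell markers 0.16 and -0.26, and the 1 endothelial marker -0.00 and 0.40. Cholangiocyte markers were not measured. The 2 erythroid markers had medians of -0.38 for heat stress and 1.21 for female minus male, and the 2 cell division genes 0.06 and 0.02. The 2 circadian clock genes had medians of -0.07 and -0.30. With so few members, a change in the share of these cells was not tested.

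The 4 female-biased genes had a median of 0.40 in females minus males and 0.32 in E+HS minus E+TN. The male-biased list had an interaction median of -0.50, with all 5 members lower (adjusted p = 0.454).

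Ribosomal proteins stood far below the reference, with a level of -2.19 in E+HS and -2.08 in E+TN, the lowest of the tested lists. With equal spread their interaction median was -1.51 (camera adjusted p = 8.15e-22), with quantile normalization -0.75 (adjusted p = 2.40e-09) and with a slope removed -0.47 (adjusted p = 0.00105), against -0.37 (adjusted p = 0.0683) in the planned setting. Without centring it was -1.47 (adjusted p = 0.0140), but all 19 lists then lay between -1.71 and -0.86. These calls use the preset correlation. With an estimated correlation the adjusted p was 0.519, 0.487, 0.997 and, without centring, 0.883, against 0.937 in the planned setting. In the planned setting the E+HS females stood at -1.65 (F232), -2.88 (F231) and -2.29 (F201) and the E+TN females at -1.58, -2.03 and -2.22. F231, the mouse with the doubted swapped array, thus lay lowest among the females. The interaction also rests on the males, among which M221 stood at -2.98. How much F231 adds under the other scalings was not tested.

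On the direct array 6 of 19 lists lay in the outer 5% of random lists, both sides together. Beside the P450 and cholesterol lists these were antioxidant genes at -0.46 (percentile 0.48, and -0.07 without removal of the dye effect), ribosomal proteins at -0.36 (percentile 1.45, and -0.14 without it), oxidative phosphorylation at -0.37 (percentile 1.84, and -0.14 without it) and bile acid genes at 0.10 (percentile 99.2, and 0.16 without it). The cholesterol list stood at 0.79 without it and the P450 list at -0.35. All these signs rest on the direction in the labels of this array.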
